A study of Mus musculus with 9 samples.

How the data were processed

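The study measured DNA methylation by whole-genome bisulfite sequencing of primordial germ cells of female WT and Tet1-null mouse embryos, with 4 and 5 libraries. Per the labels' protocols, DNA was tagged and fragmented by Tn5 transposase, converted with bisulfite by a kit from Sigma or Zymo, amplified by PCR and sequenced on an Illumina HiSeq 2000. The Sigma kit was used for 2 of the WT and 2 of the Tet1-null libraries, and the Zymo kit for 2 and 3. Libraries of sequencing run 1, 2 and 3 numbered 1, 1 and 2 for WT and 0, 2 and 3 for Tet1-null. The titles of WT libraries 1 and 3 carry a further number that the labels do not explain. The labels do not say whether libraries of a group came from separate embryos.

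The authors deposited 1 table per genotype in which libraries were pooled. It gives per CpG site the methylation level as a fraction, and, as deposited, the count of reads at the site. The product of both was a whole number of methylated reads at 100% of sites, within a tolerance of 0.0005 per read at the site. Sites are listed on 1 strand. Per the submitters' processing notes, the build was mm9 and bedtools was used. The aligner, its settings and the handling of duplicate reads are not given in the sources used here. A read filter deposited by the authors drops reads in which over 1.2% of bases are a C not followed by G, which removes poorly converted reads and can lower the levels of both pools and of chrM. Bisulfite sequencing does not separate 5-methylcytosine from 5-hydroxymethylcytosine. PCR reads without molecular identifiers are not independent molecules, so Wilson and other counting intervals cover counting error only.

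From these tables, methylated and total reads were summed over sites with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Levels are methylated reads divided by all reads, with Wilson 95% intervals. Differences of chromosomes and density classes carry 95% intervals from 2000 bootstrap draws of 1 Mb blocks. Those of chrM and of single places carry counting intervals (Newcombe). Levels by distance were taken around up to 5000 randomly drawn methylated sites per chromosome. CpG density was the number of positions listed in either table per 1 kb window, which undercounts positions with no read. Windows entered the test with at least 5 positions covered in both pools and 20 reads in each. They were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a difference of 20 points or more. This test was chosen because the tables hold read counts but no replicates. The windows named were the 5 with the largest rise and the 5 with the largest fall among those called. These choices and most alternatives were made before the data were examined. Windows at 50% or more, 1 Mb blocks and windows deeper than 20 times the median were examined afterwards.

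The procedure was tested on simulated data on the 372073 windows. With independent reads, Fisher's test recovered 14 of 100 windows changed by 30 points and 81 of 100 changed by 60 points, with 0 false calls. With reads shared by sites of the same fixed 100 bp tile, it recovered 31 and 89 and made 1431 false calls, and a quasi-binomial F test made 910. The median tested window had 27 reads in the WT pool and 36 in the Tet1-null pool.

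Promoters, the fixed gene lists (with imprinted, germline, meiotic and somatic genes), Tet1 itself and repeat-masked sequence were not analysed here, since no annotation of the build was used. The deletion of Tet1 was therefore not checked in these data. CpG sites only were used, apart from chrM as a conversion background. The alternatives were other site and window minimums, window sizes, sizes of difference, a quasi-binomial test, thinning to equal depth, leaving out the deepest 1% of sites, and autosomes alone. Those added after seeing the data left out deep windows, subtracted the chrM level, kept sites 100 bp apart, and varied the windows at 50% or more.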

Results

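Whole-genome bisulfite sequencing was used to compare DNA methylation in primordial germ cells of wild-type (WT) and Tet1-null female C57BL/6 mouse embryos at embryonic day 13.5. Primordial germ cells are the embryonic precursors of eggs and sperm, and they lose most of their DNA methylation before this age. Tet1 encodes a dioxygenase that oxidises 5-methylcytosine, and the comparison asks whether methylation differs in germ cells that lack it. The labels describe 4 WT libraries from 1575 to 5251 cells and 5 Tet1-null libraries from 1400 to 4700 cells. The labels state the same 3266 input cells for Tet1-null libraries 1 and 2, which differ in kit, and do not say whether these are separate samples. The values were available as 1 pooled table per genotype, so every difference below is between 2 pools of libraries and has no replicate check. Intervals cover counting error or the spread between 1 Mb blocks of the genome, not the spread between embryos. The WT pool listed 13730600 CpG sites with 30386353 reads over them, a mean depth of 2.21 reads per site. The Tet1-null pool listed 16372728 sites with 46716079 reads, a mean depth of 2.85. Coordinates are those of mouse build mm9, printed counted from 1 on the reading of the tables as BED; the offset of 1 base was not checked against the genome.

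Methylation was low in both pools and higher in the Tet1-null pool. Outside chrM, 3.50% of reads were methylated in the WT pool and 4.16% in the Tet1-null pool, a rise of 0.663 percentage points (95% interval from a bootstrap of 1 Mb blocks, 0.635 to 0.686) or 1.19-fold. The Wilson 95% intervals of the levels were 3.495 to 3.509% and 4.159 to 4.170%. The rise appeared at sites whose shallower pool held 1 read (0.517 points), 2 reads (0.635 points), 3 to 4 reads (0.665 points) and 5 to 9 reads (0.674 points). It turned into a fall at the 7751 sites with 10 or more reads in both pools, where the WT level was 11.3% and the Tet1-null level 9.08%. These made up 0.0681% of the sites listed in both pools. On chrM, used as a measure of cytosines left unconverted, the level was 1.66% in the WT pool and 1.29% in the Tet1-null pool.

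Each of the 19 autosomes had a higher level in the Tet1-null pool, with a block interval above 0. Autosomes together rose from 3.41% to 4.08%, by 0.674 points (0.647 to 0.697). Chromosome 11 had the smallest rise, 0.552 points (0.484 to 0.618), and chromosome 19 the largest, 0.789 points (0.697 to 0.878). Chromosome 17 rose by 0.560 points with a wide interval of 0.0651 to 0.854. The X chromosome had a higher level than the autosomes in both pools, and rose from 5.70% to 6.08%, by 0.381 points (0.254 to 0.506). The autosomal rise exceeded that of the X by 0.293 points (0.163 to 0.412). At sites with 5 or more reads in both pools this contrast turned to -0.935 points, with an interval of -2.51 to 0.698 that included 0, and it was 0.419 points (0.0286 to 0.785) at those sites without windows deeper than 20 times the median. The ratio of X to autosomal level was 1.67 in the WT pool and 1.49 in the Tet1-null pool. Mean depth per listed site on the X was 1.01 times that of the autosomes in the WT pool and 1.004 times in the Tet1-null pool.

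**Figure D1:**
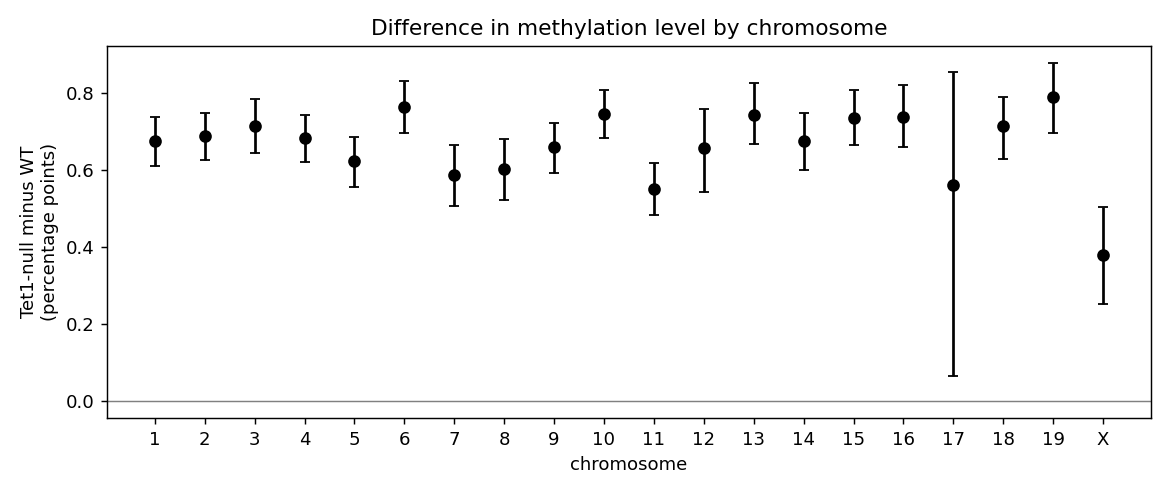
Difference in methylation level between the Tet1-null and WT pools (y axis, percentage points) for each autosome and the X chromosome (x axis), with bars for the 95% interval from a bootstrap of 1 Mb blocks. The autosomes lie between 0.552 and 0.789 points, and the X lies at 0.381 points.

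The landscape of methylation along chromosomes was shared by the pools. Across 2573 blocks of 1 Mb, the levels of both pools had a Pearson r of 0.960 and a Spearman rho of 0.899, a relation across genomic blocks, which are not independent replicates. The Tet1-null level was higher in 2234 of 2410 autosomal blocks and in 114 of 163 blocks of the X. The blocks named next were chosen after their values were seen. The block with the highest level was the distal X from 166000001 to 167000000, at 26.0% in the WT pool and 29.3% in the Tet1-null pool, and at 8.72% and 9.46% without windows deeper than 20 times the median. The largest rise was on chromosome 13 from 120000001 to 121000000, from 15.1% to 20.8%, and without 4 such deep windows the levels were 6.44% and 8.24%. The largest fall was on chromosome 17 from 39000001 to 40000000, from 18.2% to 8.55%, which rested on 7 such deep windows, since the levels without them were 11.09% and 11.14%.

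**Figure D2:**
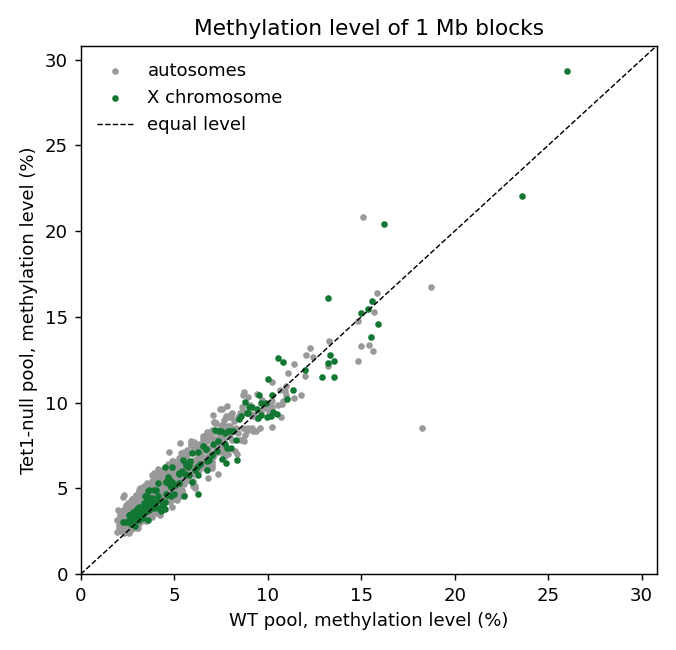
Methylation level of each 1 Mb block in the WT pool (x axis, %) and in the Tet1-null pool (y axis, %), with autosomal blocks in grey, X blocks in green and a dashed line of equal level. Most blocks lie above the line (2234 of 2410 on autosomes), and 1 autosomal block at 18.2% and 8.55% lies far below it.

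The difference depended on CpG density. Over autosomes and the X, 1 kb windows with 1 to 9 CpG positions rose from 2.98% to 3.41%, by 0.436 points (block interval 0.418 to 0.452). Windows with 10 to 19 positions rose by 0.864 points (0.838 to 0.890), and windows with 20 to 39 positions rose from 5.93% to 7.12%, by 1.19 points (1.098 to 1.27). In windows with 40 to 59 positions the levels were 3.51% and 3.46%, and the interval of the difference, -0.219 to 0.113 points, included 0. Windows with 60 or more positions fell from 4.23% to 2.91%, with a difference of -1.33 points (-2.82 to -0.347). Without windows deeper than 20 times the median, a setting chosen after seeing the data, those densest windows were at 2.57% and 2.10%, a difference of -0.465 points (-0.566 to -0.356). On the X alone, windows with 1 to 9 positions were at 4.08% and 4.15% (difference 0.0744 points, block interval -0.0134 to 0.163), windows with 10 to 19 positions rose from 8.05% to 8.74% (0.691 points, 0.441 to 0.923), and windows with 20 to 39 positions were at 18.0% and 18.8% (0.783 points, -0.0554 to 1.57). X windows with 40 to 59 positions were at 10.8% and 11.7% (0.888 points, -0.588 to 2.47). Those with 60 or more were at 9.07% and 9.14% (0.0695 points, -0.888 to 1.18), so a fall was not detectable there. These 2 X classes rested in part on deep windows. Without them the levels were 6.14% and 6.13% with 40 to 59 positions, and 2.60% and 2.76% with 60 or more.

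**Figure D3:**
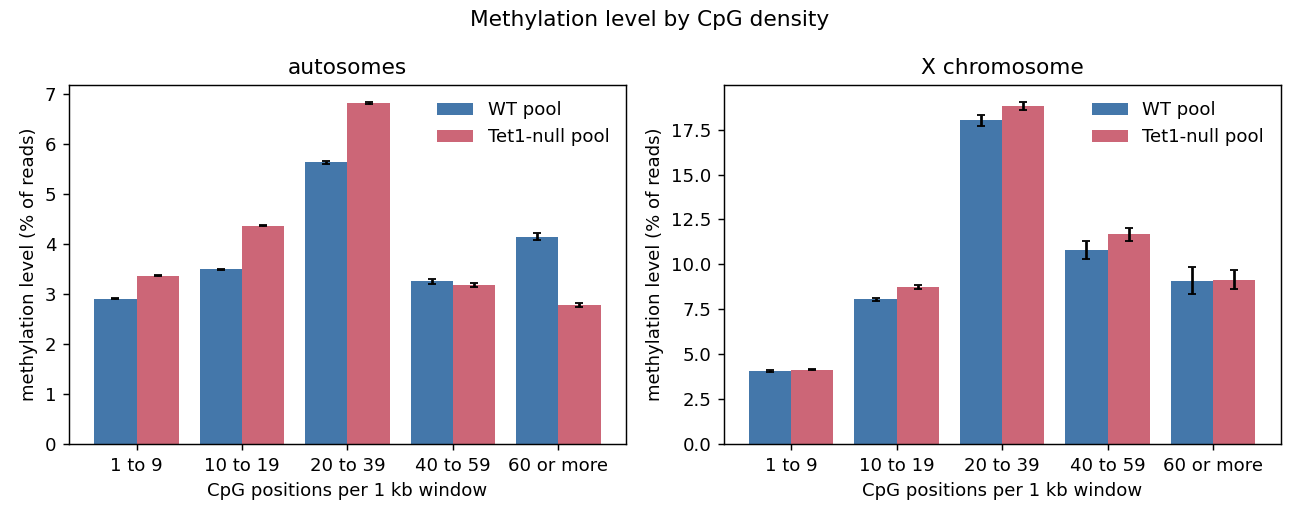
Methylation level (y axes, % of reads, with different scales) of the WT pool and the Tet1-null pool by number of CpG positions per 1 kb window (x axes), on autosomes and on the X, with Wilson 95% intervals that cover counting error. Autosomal windows with 20 to 39 positions stand at 5.63% and 6.81%, and those with 60 or more at 4.14% and 2.79%.

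Most sites with 5 or more reads in both pools held no methylated read. Of 218074 sites with 5 or more reads in both pools, 85.7% were at 0% in the WT pool (Wilson 95% interval 85.6 to 85.9%) and 82.4% in the Tet1-null pool (82.3 to 82.6%). Sites over 80% made up 0.183% (0.166 to 0.202%) and 0.171% (0.154 to 0.189%), which was not distinguishable at this depth. With reads thinned to equal depth at each site, the shares at 0% were 86.2% and 84.5%. At the 7751 sites with 10 or more reads in both pools they were 42.1% and 34.6%, without thinning. The Tet1-null pool held 343683 reads there against 193354 in the WT pool, and more reads at a site lower the share at 0%. The Tet1-null level at those sites was the lower one, 9.08% against 11.3%, so these shares do not show a gain there.

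Windows that kept methylation overlapped between the pools beyond independent lists. Of 372073 windows of 1 kb with at least 5 CpG positions covered in both pools and 20 reads in each, 2265 were at 50% or more in the WT pool and 2188 in the Tet1-null pool. Both lists held 876 of these windows, 38.7% of the WT list, where independent lists would share 13.3. In the windows retained in the WT pool the Tet1-null level was 45.5%, and in those retained in the Tet1-null pool the WT level was 44.5%. The X held such windows more often than autosomes, at 2.30% against 0.571% of tested windows in the WT pool and 2.24% against 0.551% in the Tet1-null pool.

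A test of single windows called differences in both directions. Fisher's exact test with Benjamini-Hochberg adjustment compares the reads of these 2 pools and not the genotypes. It called 361 windows higher and 237 lower in the Tet1-null pool by 20 points or more. A quasi-binomial F test called 69 and 44, and Fisher's test on reads thinned to equal depth 146 and 61. Reads of neighbouring sites are not independent. In a simulation in which sites of the same fixed 100 bp tile shared their reads, Fisher's test made 1431 false calls among the unchanged windows, against 598 windows called in the data. The simulation made all sites of a tile fully alike on a read, an extreme of dependence within tiles. It held no dependence across tiles and no duplicate reads, so it is not an upper bound for the data. It shows that such calls can be false, but not how many of the 598 are. On sites at least 100 bp apart, an alternative chosen after seeing the data, 0 of 311031 windows tested were called. Windows entered it with at least 3 such sites covered in both pools and 10 reads in each. At an unadjusted p under 0.05, 559 were higher and 797 lower, a share of those tested well under 0.05. The main setting had 9570 higher and 7098 lower at that p. The setting of spaced sites had little power, since 174 of the 598 called windows had enough such sites and reads to be tested. Of these, 115 could have passed the adjusted threshold, without other calls, by complete separation of the pools. The median level of risen windows was 1.37% in the WT pool and 44.4% in the Tet1-null pool, and that of fallen windows was 46.2% and 2.63%. By density, 180 of 63655 windows with 20 to 39 CpG positions were higher and 109 lower, against 150 and 101 of 247062 with 10 to 19 positions and 4 and 6 of 4365 with 60 or more.

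The 10 called windows with the greatest differences rested on 20 to 55 reads per pool and on 1 to 6 reads at their deepest site. Among those higher in the Tet1-null pool, the window on chromosome 3 from 107180001 to 107181000 held 1 methylated read of 27 in the WT pool and 16 of 21 in the Tet1-null pool. The window on chromosome 7 from 124259001 to 124260000 held 2 of 27 and 35 of 44 (adjusted p = 2.51e-05, Fisher's exact test). The other windows that rose were chromosome 7 from 137089001 (0% and 72.4%), chromosome 1 from 24075001 (0% and 70.0%) and chromosome 13 from 14915001 (0% and 69.1%). Among those lower, the window on the X from 31729001 to 31730000 held 21 methylated reads of 25 in the WT pool and 0 of 20 in the Tet1-null pool (adjusted p = 4.50e-05, Fisher's exact test). The remaining falls were on chromosome 3 from 66333001 (76.2% and 0%), chromosome 7 from 25345001 (75.0% and 2.22%), chromosome 17 from 56937001 (68.2% and 0%) and chromosome 9 from 19567001 (76.2% and 8.33%). By a quasi-binomial F test, 4 of the 10 were no longer called: chromosome 3 from 107180001 (adjusted p = 0.316), chromosome 7 from 137089001 (0.0832), chromosome 13 from 14915001 (0.106) and chromosome 9 from 19567001 (0.230). On sites 100 bp apart only the chromosome 13 window had enough sites and reads to be tested, at 0% of 10 and 36.4% of 11 reads, too few to pass the adjusted threshold at any difference. Whether these windows lie in genes was not analysed here.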

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

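The tests by chrM and of the dense windows were chosen after the result was seen, and the test by methylation of flanking windows before. The value at sites in both pools was planned, but its bound was set after it was seen. Signal appeared outside the main measurement on chrM, at 1.66% in the WT pool and 1.29% in the Tet1-null pool, and on chrY, at 11.9% of 915 reads and 12.4% of 2418 reads in pools labelled female.

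The higher genome-wide level of the Tet1-null pool was weighed against 3 explanations. Unconverted cytosines argue the other way, since the chrM difference was -0.371 points (counting interval -0.537 to -0.211). A rise of 0.608 points at sites listed in both pools argues against a different set of sites as the whole cause. Those sites still weigh by their reads in each pool. The mean of site levels, at sites with 5 or more reads in both, rose by 0.383 points, so a part from unequal depth is not excluded. A larger share of somatic cells, which are more methylated, stays open. It was tested in autosomal windows of 1 to 9 CpGs only. Beside windows under 2% their rise was 0.433 points, and beside windows at 20% or more the difference was -0.277 points (-0.540 to 0.00533). Top minus 2 times bottom was thus -1.14 points (-1.41 to -0.860). A smaller rise beside windows at 20% or more was the outcome set beforehand for a somatic share. Other values go against it as the whole cause, since windows of 1 to 9 CpGs rose by 0.436 points and the more methylated windows of 20 to 39 CpGs by 1.19 points, and with 5 or more flank reads in each pool, both pools weighted equally and deep windows left out, the difference beside windows at 20% or more was -0.455 points (-0.721 to -0.167), a fall that added methylated cells would not bring, although it lies within the counting interval of the chrM difference. No somatic profile or marker was tested, the labels used here name no sort, kit and run cannot be told apart from genotype in pooled tables, and an effect of the genotype stays open.

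The lower level of CpG-dense windows came in large part from a single deep cluster, with a smaller fall left in the other dense windows. A cluster of 6 windows on chromosome 17 from 39980001 to 39986000, at about 350 and 434 times the median depth, was at 20.6% in the WT pool and 7.92% in the Tet1-null pool, and of all 96 deep clusters 15 were lower in the Tet1-null pool and 7 higher with a counting interval that excluded 0. Without windows of such depth the difference in the densest windows shrank to -0.465 points, and without that cluster alone it was -0.473 points. At the level seen on chrM, unconverted cytosines are too few to account for the cluster, whose difference was -12.7 points. The chrM level cannot show whether conversion failed locally in the cluster, so that stays open. The -0.465 points in the other dense windows lie within the counting interval of the chrM difference and may be a conversion background. What the deep cluster is was not tested, and a difference between the genotypes there stays open.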

How the results depend on the processing

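Those without deep windows, with chrM subtracted, on sites 100 bp apart and for windows at 50% or more were added after seeing the data. No paired analysis was possible and leaving out libraries was not run, since the tables pool each genotype's libraries. Each strand alone, promoters, gene lists and repeats were not run. Of the alternatives to the main values and counts, 28 stayed within the 95% interval of the main value, or within 1.5 times of a count, 24 moved out of it, 14 counts became smaller by over 1.5 times and 3 reversed a difference whose interval excluded 0. The class of 40 to 59 CpGs and the share of sites over 80%, whose counting intervals included 0, also changed sign, the latter to 0.00711 points with 3 reads. For the named windows, 26 alternatives kept the call and 5 lost it, 4 by the quasi-binomial test. The other loss was on chromosome 13, on sites 100 bp apart, where 10 and 11 reads could not have passed. Of those kept, leaving out the top 1% of depth could change no window, since no site held over 6 reads. No named window could be tested at sites with 3 or more reads in both pools. The causes were not tested except where stated.

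The genome-wide rise became 0.383 points as a mean of site levels, 0.608 at sites in both pools, 0.674 on autosomes and 1.03 with the chrM level subtracted. It reversed to -2.24 points at sites with 10 or more reads in both pools, and to -0.583 points there without deep windows, so deep windows account for part of the reversal and the cause of the rest was not tested. The autosomal rise was 0.512 at sites with 5 or more reads, 0.684 without the top 1% of depth and 0.685 without deep windows, and that of the X 1.45 at sites with 5 or more reads. There the autosomal rise minus that of the X reversed to -0.935 points, and was 0.419 without deep windows, so those windows turn it.

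At sites with 5 or more reads in both, the density classes from sparse to dense differed by 0.332, 0.906, 1.55, 0.953 and -9.96 points, and with 500 bp windows by 0.380, 0.706, 1.25, 0.883 and -0.926 points. The densest class was at -0.460 without the top 1% of depth and -0.465 without deep windows. The class of 40 to 59 thus had no settled sign. The difference in the share of sites at 0% was -2.84 points with 3 reads, -7.48 with 10 reads and -1.71 with thinning, and that over 80% was -0.142 with 10 reads. The values with 3 and 10 reads were not thinned, so the greater depth of the Tet1-null pool can lower its share at 0%.

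Windows higher and lower numbered 195 and 126 at 40 points, 69 and 44 by the quasi-binomial test and 146 and 61 with thinning. Each of these settings tested 372073 windows. With 50 reads they numbered 100 and 52 of 17150 tested, and at sites with 3 reads 86 and 37 of 30901. Those counts came from far fewer windows tested and are not a lower rate of calls. On sites 100 bp apart they were 0 and 0 of 311031 tested. That setting had little power, and 115 of the 598 called windows could have passed at all. The share of calls that were higher ran from 52.1% with 10 reads to 70.5% with thinning. Windows at 50% or more in both pools numbered 105 of 17150 tested with 50 reads and 570 of 607264 tested of 2 kb. The main setting had 876 of 372073.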

Other observations

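All patterns in this part were noticed in the data, and the tests of the windows' flanks and of spaced sites were set before their results were seen, while the controls with equal read numbers and the test of the X against autosomes were chosen after. Methylation clustered around sites methylated in the other pool. At sites with a methylated WT read the Tet1-null level was 11.9%, against 3.46% at sites without one. Around autosomal sites methylated in the WT pool, the Tet1-null level was 9.18% at a distance over 300 and up to 1000 bp and 7.23% from there to 3000 bp. It was 5.46% to 10000 bp and 4.48% to 30000 bp, against 4.08% over all autosomes. That mean is not matched for CpG density. The Tet1-null level of autosomal windows was 3.37% with 1 to 9 positions and 6.81% with 20 to 39, so the excess was not separated from density.

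Dense windows that kept methylation in both pools numbered 49 among windows with 40 or more CpG positions, where independent lists would share 0.517. A window on chromosome 8 from 93947001 to 93948000, chosen after its values were seen, was at 90.0% of 50 reads in the WT pool and 78.8% of 85 reads in the Tet1-null pool. Deep places chosen after their values were seen included single windows that were lower in the Tet1-null pool, on chromosome 16 from 57391001 (17.3% and 6.92%) and from 11144001 (25.1% and 9.72%), on chromosome 3 from 5860001 (15.3% and 7.27%) and on chromosome 18 from 68851001 (29.8% and 3.72%). A deep cluster on chromosome 13 from 120277001 to 120282000 was at 44.5% and 52.7%, and one on the X from 166415001 to 166436000 was at 40.6% and 43.6%.

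On the X, 5 called windows were higher and 17 lower, against 356 and 220 on autosomes (p = 0.000485, Fisher's exact test, two-sided, over windows that are not independent). Over the other settings that made calls, this p ran from 0.000536 to 0.240, so the contrast rests on the setting.

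Single windows were called in both directions, and if a called window reflected a wider change rather than few molecules, its flanks at 200 to 1000 bp would differ by 5 points or more the same way. Flanks of risen windows differed by 3.71 points (2.15 to 5.29) and those of fallen windows by 1.65 points (-0.258 to 3.50), the opposite sign to the windows. Both lay under the bound of 5 points, the outcome set for few molecules, though the interval of the risen flanks passed it. A difference confined to the window would leave the same flanks, so the test cannot tell it from few molecules. A wider change stays open for a part of the rises. On sites 100 bp apart, 16.6% of the 598 called windows kept an unadjusted p under 0.05 in the same direction, while as many random reads of the same windows kept 39.1% (33.4 to 42.5% over 100 draws) and random reads of sites covered in both pools kept 38.9%. Loss of reads alone thus misses the bound of 50% set beforehand but does not reach 16.6%, which suggests that shared reads, or methylation shared by neighbouring sites, add to the calls. A difference between the genotypes in single windows remains untested without replicates.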
